A study of Bacillus subtilis subsp. subtilis str. 168 with 6 samples.

How the data were processed

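Total RNA of B. subtilis 168 biofilms grown on agar, in 3 wild-type and 3 ΔsamI libraries, was depleted of rRNA and made into stranded Illumina libraries that were sequenced from both ends with reads of 50 nt, per the labels' protocols. Trimmomatic 0.39, Bowtie2 2.3.2, featureCounts 2.0.0 and DESeq2 are named, per the submitters' processing notes. The genome build, the annotation and the strand setting of the counting were not given in the sources used here, so counts of overlapping or antisense genes are uncertain. The deposited table of raw counts held whole numbers for 4448 genes and was the input of every test. The second deposited table held signal, each value being the raw count divided by 1 factor per library, which equalled median-of-ratios size factors computed over its 4073 genes. That table was used only for this comparison. The 375 genes missing from it were those without at least 10 counts in at least 3 libraries, which sorted all genes with 0 exceptions.

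Groups were taken from the genotype in the labels, and 0 columns of values lacked a sample. The design calls the libraries biological replicates. Locus tags were matched to the RefSeq table of assembly ASM904v1, which named all 4448 genes and was used only for names and gene order. Coordinates are not printed because the count table names no build. Symbols carried by more than 1 locus were assigned to the locus nearest the other members of a list. Of 878 list members 812 (92.5%) matched a name. Members listed under a name other than the reference's were not tested in their list, such as int, the integrase gene ydcL.

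Total counts ran from 5551793 to 6954820 per library. Counts normalised to library size (CPM) were computed with TMM-scaled library sizes. A level of 3 counts, the upper limit that a count of 0 allows, corresponded to 0.431 to 0.540 CPM of the total counts, without TMM scaling. Such limits and exact intervals at the 95% level cover counting error only. In R 4.3.3, edgeR 4.0.16 tested the mutant against the wild type by its quasi-likelihood test with robust dispersion, after its default expression filter and TMM normalization, with Benjamini-Hochberg adjustment and a threshold of 0.05. On counts simulated for 3997 genes from this comparison's means and library sizes, it recovered 41 of 100 genes changed 2-fold and 91 of 100 changed 4-fold, with 4 false calls. Before the data were examined, 45 gene lists were fixed, and 44 with at least 3 tested members were tested by camera of limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and adjustment over lists. The deleted gene was left out of every list. Each list also received counts of members past the threshold, over all genes and adjusted over the list alone.

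Genes to be named were also fixed before the data were examined. The rule took samI, its operon and the next gene on each side. It added the 10 largest changes in each direction among called genes with a mean of at least 5 CPM and no overlap between the groups. From each called list it took the 3 members with the smallest p, and from lists of the biofilm cell states the member with the smallest p. The main fit had no replicate block, since the labels tie no number to a shared day or batch. Alternatives were RLE factors, total counts, DESeq2 1.42.0, limma-voom, no filter, a minimum of 50 counts in 3 libraries, the replicate number as a block, rRNA and tRNA genes left out, a test against a 1.2-fold change and each library left out in turn. For lists they were an estimated correlation, fry, camera on the edgeR statistics themselves, the block and RLE factors. The filter of 10 counts in 3 libraries and the omission of both libraries numbered 1 were chosen after seeing the data. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.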

Results

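RNA was sequenced from biofilms that Bacillus subtilis strain 168 formed on agar, in the wild type and in a mutant that lacks samI (ydjI, locus tag BSU_06210). This gene encodes a member of the SPFH family, membrane proteins that include the flotillins. Each strain was represented by 3 libraries, which the labels call biological replicates. Comparing the strains asks how loss of this protein alters gene expression in a biofilm, in a study whose title concerns membrane stress and differentiation. Counts summed to 6149586, 6954820 and 6748305 in wild-type replicates 1 to 3 and to 6310519, 6815215 and 5551793 in the mutant replicates. The table listed 4448 genes, of which 4061 had enough counts to be tested. Libraries of the same strain differed beyond sampling noise, with a chi-square per degree of freedom between 26.0 and 93.7, so each was counted as 1 sample. The first principal component, with 55.6% of the variance, separated the strains. The second, with 21.2%, set the library numbered 1 of each strain apart from the others.

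The deleted gene was nearly absent from the mutant libraries, while the genes beside it did not pass the test. Counts of samI were 1076, 1179 and 799 in the wild type and 18, 16 and 7 in the mutant. Normalised to library size as CPM, its level was 143 ± 34.9 in the wild type and 2.40 ± 1.09 in the mutant (SD, n = 3 libraries each), which left 1.67% of the wild-type mean. The log2 fold change was -5.89 (SE 0.38, edgeR adjusted p = 4.17e-05). An exact 2-sided permutation test of the mean log2(CPM + 1) gave p = 0.1, the smallest value that the 20 regroupings of 3 against 3 libraries allow. The gene is the last of an operon read by the membrane-stress sigma factor SigW. Its partners pspA, which encodes a phage-shock protein, ydjG and ydjH had log2 fold changes of 0.20 (SE 0.26), 0.04 (SE 0.32) and 0.26 (SE 0.34), with edgeR adjusted p of 0.742, 0.964 and 0.74. None of these 3 partners passed at an unadjusted p under 0.05, in DESeq2 or in limma-voom, and their median of 0.20 turned to -0.05 when libraries were scaled by total counts and ran from -0.16 to 0.39 when each library was left out in turn. On the far side of pspA, ydjE stood at -0.02 (adjusted p = 0.968). On the other side, ydjJ had 8, 16 and 4 counts in the wild type and 3, 2 and 4 in the mutant, too few to be tested.

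**Figure D1:**
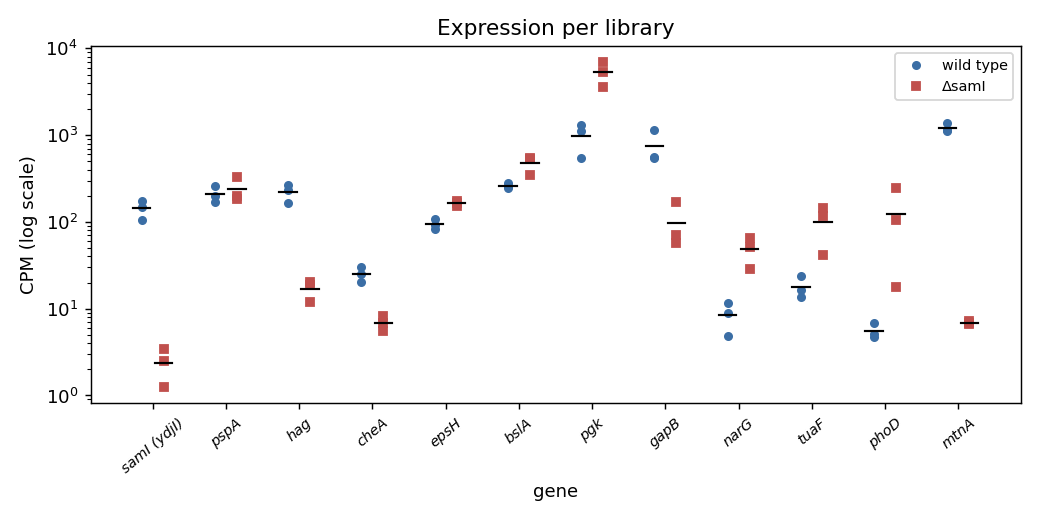
Expression of 12 genes in each library, in CPM on a log axis. Circles are the 3 wild-type libraries, squares the 3 mutant libraries, and short lines the group means. For samI, hag, cheA, gapB and mtnA every mutant library lies below every wild-type library, and for epsH, bslA, pgk, narG, tuaF and phoD every mutant library lies above, although bslA missed the threshold (edgeR adjusted p = 0.0505). For pspA the groups overlap.

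Across the transcriptome 179 genes differed between the strains at an edgeR adjusted p under 0.05, 72 of them higher and 107 lower in the mutant. The genes that rose included 42 protein-coding genes, led by phosphate starvation, nitrate respiration and glycolysis genes, and all 30 rRNA genes. The genes that fell comprised 103 protein-coding genes and 4 other RNA genes, among them genes of the conjugative element ICEBs1, of methionine salvage and of motility. A change of at least 2-fold was seen for 160 genes, 66 higher and 94 lower, and 847 genes had an unadjusted p under 0.05. For all 179 genes the CPM of the groups did not overlap, which held for 1114 (27.4%) of all genes tested and is reached by chance in 10%. Genes named outside the fixed rule, such as ydcL, yorD, gapA, citZ, abrB, epr, groEL and glpT, were chosen after their values were seen. Scaling by total counts moved the median log2 fold change of all genes from 0.00 to -0.23 and gave 56 higher and 204 lower genes, and leaving out rRNA and tRNA genes gave 36 higher and 88 lower. The count fell to 59 without mutant replicate 2, to 89 without wild-type replicate 1, to 91 without mutant replicate 1 and to 33 (2 higher, 31 lower) without both libraries numbered 1, a setting chosen after seeing the data. Of the 179 genes, 56 passed when each library was left out in turn. Counts of list members below refer to the main edgeR fit where no other setting is named, and the alternatives changed many of them in either direction.

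**Figure D2:**
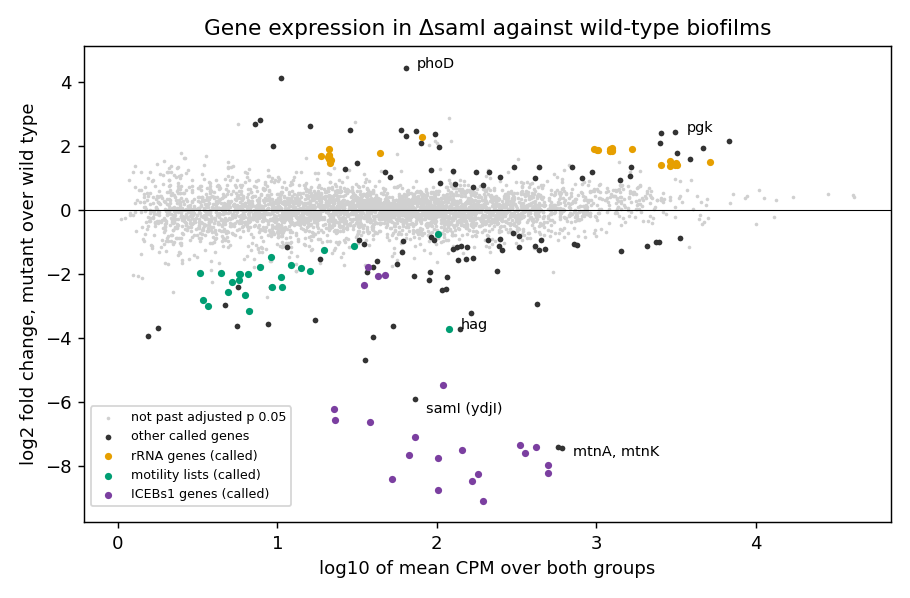
Log2 fold change of each tested gene, mutant over wild type, against the log10 of its mean CPM over both groups. Grey points missed an adjusted p of 0.05, black points passed it, and coloured points are rRNA, motility-list and ICEBs1 genes that passed. ICEBs1 genes reach -9.08, mtnA and mtnK lie at -7.45 and -7.41, and phoD has the highest value among the called genes, 4.45.

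The 10 largest decreases among the genes chosen by the fixed rule all lay in ICEBs1, an integrated element of strain 168 that can excise and transfer by conjugation. All 18 protein-coding genes from xis to yddI fell, with log2 fold changes from -9.08 to -5.48. The excisionase gene xis fell from 996 ± 83.5 to 3.29 ± 1.38 CPM (SD, n = 3 libraries each), a log2 fold change of -8.23 (SE 0.32, edgeR adjusted p = 3.17e-06). For conB, a gene of the conjugation machinery, the change was -9.08 (SE 0.41, adjusted p = 6.32e-06), and for the relaxase gene nicK it was -8.46 (SE 0.60, adjusted p = 8.34e-05). The other genes picked by the rule were conC (-8.74), ydcS (-8.40), BSU_04849 (-8.27), ydzL (-7.96), conD (-7.74), ydcT (-7.66) and helP (-7.59). Genes at the ends of the element moved less. The repressor gene immR fell by 2.34 on the log2 scale (adjusted p = 0.0018), immA by 2.07 and the integrase gene ydcL by 2.03, and yddJ fell by 1.77, whereas yddK (-0.81), rapI (0.30), phrI (0.22) and yddM (-0.56) did not pass. The yddJ call was lost without wild-type replicate 1, wild-type replicate 2 or mutant replicate 2. Between ydcO and BSU_04849, the annotated RNA sncO (-0.89, edgeR adjusted p = 0.419) did not pass, with 29 counts in the mutant and 70 in the wild type. In all, 22 of 27 tested genes of the element fell. The list of SPbeta prophage and ICEBs1 genes had 8 lower and 0 higher members of 22 tested, of which yddA (-7.09) and conE (-7.49) followed xis in order of p, and 1 higher and 10 lower when adjusted over the list alone. Of these 8 members, yorD (-1.21) belongs to SPbeta and the others to ICEBs1. The list holds only part of SPbeta. Among called genes in no list, its genes yonU (-1.23, edgeR adjusted p = 0.00801), yoyJ (-1.32), spbT (-1.05), yoqW (-0.93) and aacD (-0.80) were lower. The SPbeta genes nukF (1.02) and yokE (1.28) were higher. The yonU call was lost only without mutant replicate 2, and those of the others without wild-type replicate 1, mutant replicate 1 or mutant replicate 2. Limma's camera test gave the list an adjusted p of 0.000164, and an adjusted p = 0.662 with an estimated correlation. The yorD call held only without wild-type replicate 3, where 2 other members rose, and 6 members fell without both libraries numbered 1. DESeq2 and total counts gave 9 lower, limma-voom 8, and edgeR with the replicate number as a block 1 higher and 8 lower.

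**Figure D3:**
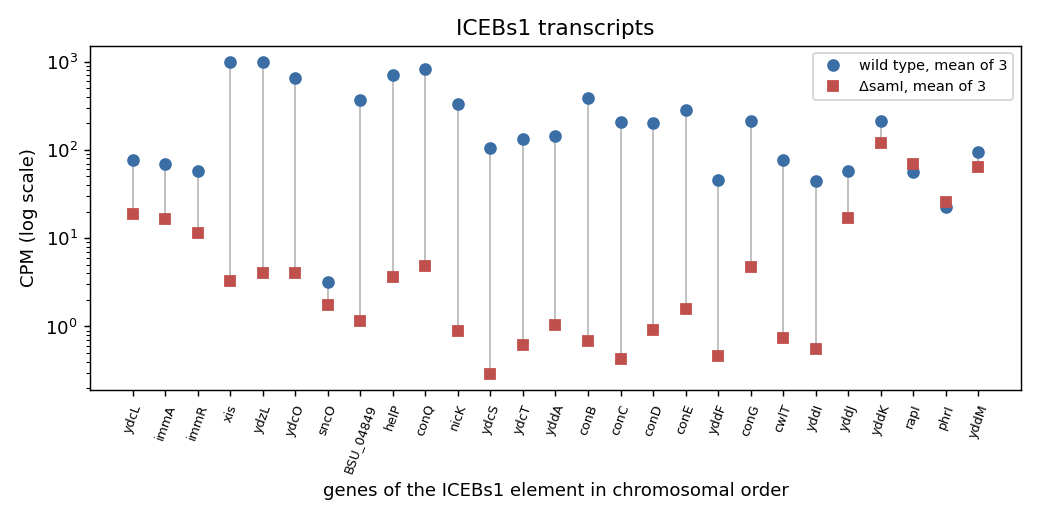
Mean CPM of 3 libraries per strain, on a log axis, for the genes of ICEBs1 in chromosomal order. Circles are the wild type, squares the mutant, and grey lines join the means of a gene. From xis to yddI the protein-coding genes lie between 44.6 and 999 CPM in the wild type and between 0.287 and 4.84 CPM in the mutant, whereas yddK, rapI, phrI and yddM lie close together.

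Several genes of methionine salvage, which recovers methionine from methylthioadenosine, were lower in the mutant. This pathway had no list of its own and was tested only as part of sulfur amino acid synthesis. The kinase gene mtnK fell from 1139 ± 97.6 to 6.67 ± 0.525 CPM and the isomerase gene mtnA from 1208 ± 149 to 6.90 ± 0.312 CPM (SD, n = 3 libraries each). Their log2 fold changes were -7.41 (SE 0.21) and -7.45 (SE 0.22), with the smallest edgeR adjusted p of all genes, 4.08e-07 for both. Of the 28 tested genes of sulfur amino acid synthesis 6 fell and 0 rose, with 10 lower when adjusted over the list alone. All 6 belong to methionine salvage, with mtnD at -2.20 (adjusted p = 0.00415), mtnB at -2.46, mtnX at -2.51 and mtnW at -2.08. The list's median was -0.39, between -0.67 and -0.19 when each library was left out in turn. The camera test of the list had an adjusted p of 1.58e-05, and an adjusted p = 0.662 with an estimated correlation. The count of 6 also stood without both libraries numbered 1 and in limma-voom, while it was 8 in DESeq2 and 10 with total counts or the block.

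Motility genes were lower in the mutant. In the fla/che operon, which encodes the flagellar basal body and chemotaxis proteins, 19 of 31 tested genes fell and 0 rose. All 31 values were negative (median -1.78), and all 31 passed as lower when adjusted over the list alone. The hook gene flgE changed by -2.42 (SE 0.34, edgeR adjusted p = 0.0071), the chemotaxis kinase gene cheA by -1.90 (SE 0.27, adjusted p = 0.00732) and ylxF by -3.15 (SE 0.46, adjusted p = 0.00801). Of 24 tested genes of the SigD regulon, the late motility genes and autolysins, 5 fell and 0 rose, and 18 were lower when adjusted over the list alone. The flagellin gene hag fell from 223 ± 51.4 to 17.0 ± 4.58 CPM (log2 fold change -3.72, adjusted p = 0.00013, n = 3 libraries each). The stator genes motB and motA changed by -2.67 (SE 0.40, adjusted p = 0.00873) and -3.01 (SE 0.61, adjusted p = 0.0283), the latter from 6.59 to 0.792 CPM and not past the threshold in limma-voom (adjusted p = 0.0598). Camera gave the lists adjusted p of 3.53e-19 and 7.91e-12, and an adjusted p = 0.501 with an estimated correlation for each. The calls were 3 and 1 without mutant replicate 2, 4 and 2 without wild-type replicate 1, 8 and 2 without mutant replicate 3, 9 and 2 without wild-type replicate 2, 8 and 3 without mutant replicate 1, and 0 and 1 without both libraries numbered 1, where the medians were -1.76 and -1.0. They were 23 and 14 in DESeq2, 15 and 3 in limma-voom, 23 and 10 with total counts and 22 and 14 with the block.

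Biofilm matrix genes had small positive values. All 19 tested genes for the exopolysaccharide, the TasA amyloid fibre and the BslA hydrophobin lay above 0, with a median of 0.60. By edgeR 3 of them rose, epsL (0.83, SE 0.18, adjusted p = 0.0393), epsH (0.80, SE 0.17, adjusted p = 0.0349) and epsK (0.73, SE 0.15, adjusted p = 0.0341), and 10 did so when adjusted over the list alone. For epsH the level was 94.1 ± 12.7 CPM in the wild type and 164 ± 11.6 in the mutant (SD, n = 3 libraries each). Values for tasA (0.43, adjusted p = 0.33) and bslA (0.86, adjusted p = 0.0505) did not pass. In limma's camera test the adjusted p was 1.49e-08, and an adjusted p = 0.501 with an estimated correlation. The 3 single-gene calls ended when libraries were scaled by total counts, where the median was 0.36, and in the test against a 1.2-fold change (edgeR adjusted p of 0.0751 to 0.081), and at most 1 member passed when any library was left out, whereas 8 rose in DESeq2, 3 in limma-voom and 13 with the replicate block. Of 9 tested biofilm regulators, 1 fell, abrB, which encodes a repressor of stationary-phase genes (-1.54, SE 0.31, adjusted p = 0.0297), and camera gave the list an adjusted p of 0.658. With total counts 2 regulators were lower. The abrB call was lost without wild-type replicate 1, wild-type replicate 2, wild-type replicate 3 or mutant replicate 3.

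Part of the glycolysis list, which includes the pyruvate dehydrogenase genes, rose in the mutant. Of 15 tested genes 9 rose and 0 fell, 10 rose when adjusted over the list alone, and all 15 values were positive with a median of 1.06. Phosphoglycerate kinase, pgk, rose from 984 ± 395 to 5291 ± 1693 CPM (SD, n = 3 libraries each), a log2 fold change of 2.43 (SE 0.38, edgeR adjusted p = 0.0104). Triosephosphate isomerase, tpiA, rose by 2.39 (SE 0.35, adjusted p = 0.00801) and the pyruvate dehydrogenase gene pdhB by 1.35 (SE 0.18, adjusted p = 0.0059). The other 6 were gapA, pgm, eno and the further pyruvate dehydrogenase genes pdhA, pdhC and pdhD. Pyruvate kinase, pyk (0.35, adjusted p = 0.298), did not pass, and neither did pgi, pfkA, fbaA, cggR or ptsG, so the calls do not cover the whole pathway. By camera the list had an adjusted p of 7e-10, and an adjusted p = 0.509 with an estimated correlation. The count was 3 without mutant replicate 2, 5 without mutant replicate 1, 6 without wild-type replicate 1 or wild-type replicate 3, and 0 without both libraries numbered 1, where the median was 1.01. DESeq2, limma-voom and the block gave 9, and total counts 8. The citrate cycle list had 1 lower member of 11, the citrate synthase gene citZ (-0.87, adjusted p = 0.0415), a call lost when any 1 of the 6 libraries was left out, and camera gave an adjusted p of 0.239. In respiration and ATP synthase no member of 25 passed in edgeR, DESeq2 or limma-voom, 3 had an unadjusted p under 0.05, and camera gave an adjusted p of 0.863.

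The 4 genes of nitrate reductase, used for respiration when oxygen is scarce, rose from low levels. The log2 fold changes were 2.80 for narJ (SE 0.53, edgeR adjusted p = 0.0232), 2.70 for narI (SE 0.34, adjusted p = 0.00347), 2.64 for narH (SE 0.45, adjusted p = 0.0157) and 2.51 for narG (SE 0.40, adjusted p = 0.012). For narG this was 8.48 ± 3.38 CPM in the wild type and 48.3 ± 18.5 in the mutant (SD, n = 3 libraries each). They were the only members of the oxygen limitation list to pass of 18 tested. The list's median was -0.02 (-0.09 to 0.38 with each library left out), its mean 0.41, and camera gave an adjusted p of 0.239. Only narI passed without mutant replicate 2, 3 of the 4 passed without wild-type replicate 1, 2 or 3 or mutant replicate 1, and 0 passed without both libraries numbered 1. The list itself passed camera without wild-type replicate 3 (adjusted p = 0.0146).

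Some phosphate starvation genes were higher in the mutant, by large and variable amounts. Of 18 tested genes 5 rose and 0 fell, 10 rose when adjusted over the list alone, and the median was 2.07 (1.3 to 2.55 with each library left out). The phosphodiesterase gene phoD had the largest increase of the fixed rule, 4.45 (SE 0.82, edgeR adjusted p = 0.0212), from 5.56 ± 1.16 to 122 ± 114 CPM (SD, n = 3 libraries each). Its neighbour tatAD, which encodes part of a protein export system, changed by 4.14 (SE 0.88, adjusted p = 0.0352). When each library was left out in turn, the tatAD call was kept only without mutant replicate 3, and it ended with no filter (edgeR adjusted p = 0.0519). Genes for teichuronic acid, a cell wall polymer without phosphate, followed, with tuaF at 2.50 (SE 0.44, adjusted p = 0.0192), tuaH at 2.47 (SE 0.54, adjusted p = 0.038) and tuaE at 2.39 (SE 0.44, adjusted p = 0.0214). The regulator genes phoP and phoR did not pass. In mutant replicates 1 to 3 phoD stood at 106, 243 and 17.9 CPM. Limma's camera put the list at an adjusted p of 4.56e-05, and an adjusted p = 0.793 with an estimated correlation. No member passed in edgeR without wild-type replicate 2, wild-type replicate 3, mutant replicate 1, mutant replicate 2 or both libraries numbered 1, 1 passed without wild-type replicate 1, and 8 passed without mutant replicate 3. With the replicate block, edgeR no longer called phoD (adjusted p = 0.0619), tuaH (0.116) or tuaE (0.0825). The tuaH call also ended with no filter (edgeR adjusted p = 0.0565) and without rRNA and tRNA genes (0.0515). DESeq2 called 9 members as higher, total counts 5, the block 1 and limma-voom 2, the last without phoD (adjusted p = 0.122), tatAD (0.185) and tuaH (0.104).

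**Figure D4:**
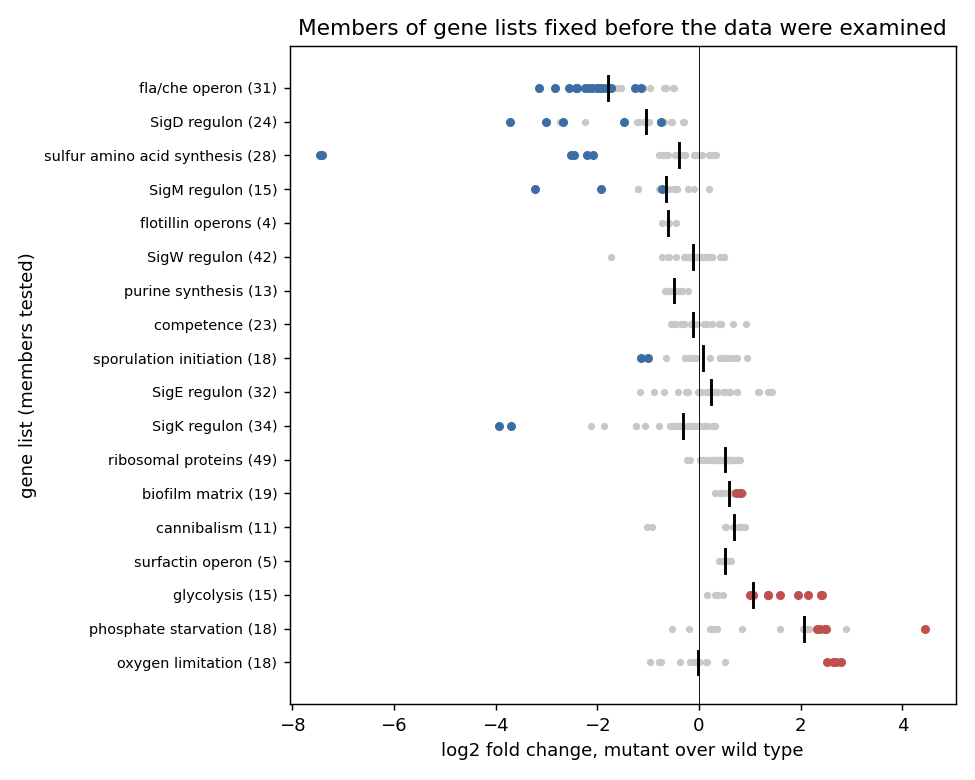
Log2 fold changes, mutant over wild type, of the tested members of 18 gene lists, with the number tested in brackets. Red and blue points are members higher or lower at an edgeR adjusted p under 0.05, grey points did not pass, and vertical lines are list medians. The fla/che median is -1.78, the glycolysis median 1.06 and the phosphate starvation median 2.07, whereas the SigW median is -0.11 and the competence median -0.11.

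Genes of the cell envelope stress responses mostly did not pass. Of 42 tested genes of the SigW regulon, which answers membrane stress and includes the operon of samI, none passed in edgeR or limma-voom, while 3 were lower in DESeq2 and 4 higher and 5 lower genes had an unadjusted p under 0.05. Camera gave this list an adjusted p of 0.593. Without wild-type replicate 2, 1 SigW gene was lower, with total counts 2 were lower, and with the block 2 were higher. The member of this list with the smallest p was the flotillin gene floT (-0.73, SE 0.21, edgeR adjusted p = 0.0952). The flotillin operons had 4 tested genes, with floT followed by yqfB (-0.61, adjusted p = 0.108) and yuaI (-0.58, adjusted p = 0.14), and a median of -0.60. None of the 4 passed in edgeR or limma-voom, 2 were lower in DESeq2 and in edgeR with total counts, and all 4 were lower at an unadjusted p under 0.05 and when adjusted over the list alone. Camera gave an adjusted p of 0.00557, and an adjusted p = 0.767 with an estimated correlation. In the SigM regulon 3 of 15 genes fell, yebC (-3.22, SE 0.37, adjusted p = 0.0025), yqjL (-1.92, SE 0.35, adjusted p = 0.0208) and the division gene divIC (-0.72, SE 0.15, adjusted p = 0.0339), and 7 fell when adjusted over the list alone. The listed ywaC was not tested in its list, because the reference names its locus relQ, which fell (-1.56, edgeR adjusted p = 0.029). When each library was left out in turn, the relQ call was kept only without wild-type replicate 2. The camera test of the list had an adjusted p of 2.27e-05, and an adjusted p = 0.793 with an estimated correlation. The SigM count was 5 without wild-type replicate 2, 2 without wild-type replicate 1 or 3, 1 without any of the 3 mutant libraries and 0 without both libraries numbered 1, against 7 in DESeq2 or with the block, 6 with total counts and 3 in limma-voom. In the test against a 1.2-fold change divIC did not pass (edgeR adjusted p = 0.081). The LiaRS operon, SigX regulon, SigV operon, peptide antibiotic transporters and pspA operon partners had no member past the threshold in edgeR, DESeq2 or limma-voom, 1 transporter gene had an unadjusted p under 0.05, and camera gave adjusted p of 0.593, 0.51, 0.726, 0.673 and 0.726. The SigX list passed camera without wild-type replicate 1 (adjusted p = 0.0449).

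Sporulation and competence genes mostly did not pass. Of 18 tested genes of sporulation initiation 2 fell, phrA (-1.13, SE 0.20, edgeR adjusted p = 0.0197) and rapA (-0.996, SE 0.21, adjusted p = 0.0335), which encode an inhibitory peptide and the phosphorelay phosphatase it blocks. With adjustment over the list alone 3 were higher and 3 lower, and camera gave an adjusted p of 0.823. Both calls were lost without wild-type replicate 1, mutant replicate 1, mutant replicate 2 or both libraries numbered 1, and that of rapA also without wild-type replicate 2 or mutant replicate 3. In DESeq2 2 were higher and 3 lower, with the block 3 and 3, and in limma-voom or with total counts 0 and 2. In the SigF, SigE and SigG regulons none of 12, 32 and 26 tested genes passed in edgeR or limma-voom, 2 SigE genes were lower in DESeq2, with total counts and with the block, and 1, 4 and 1 genes had an unadjusted p under 0.05. Camera gave these lists adjusted p of 0.658, 0.239 and 0.876, and their members with the smallest p were sigG (0.78, adjusted p = 0.146), spoVD (-1.16, adjusted p = 0.0689) and spoVAF (-0.67, adjusted p = 0.114). The spoVD value passed without mutant replicate 3 (-1.48, adjusted p = 0.0413). Of 34 tested SigK genes, which include those of the spore coat, cotZ and cotV fell and 4 were lower when adjusted over the list alone. Both rest on few counts. The mutant libraries held 3 cotZ counts against 64 in the wild type, a ratio of 0.0498 (exact 95% interval 0.01 to 0.152). For cotV they held 4 counts against 69, a ratio of 0.0616 (0.0163 to 0.165). These ratios were scaled by total counts, and the main fit gave folds of 0.0659 and 0.0770. Next came cotY (-2.11, adjusted p = 0.0594). In limma's camera test the adjusted p was 0.0118, and an adjusted p = 0.501 with an estimated correlation. The SigK count was 0 without wild-type replicate 1, wild-type replicate 2, mutant replicate 2 or both libraries numbered 1, 1 without mutant replicate 1 or 3, and 4 without wild-type replicate 3, and the cotV call also ended with no filter (edgeR adjusted p = 0.0519), against a 1.2-fold change (0.0573) or without rRNA and tRNA genes (0.0611). Total counts gave 4 lower SigK genes, the block 3, and DESeq2 and limma-voom 2. None of 23 competence genes passed in edgeR, DESeq2 or limma-voom, 2 had an unadjusted p under 0.05, the smallest p was that of comEB (-0.54, adjusted p = 0.211), and camera gave an adjusted p of 0.662.

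Toxin and lipopeptide genes had positive medians without single genes past the threshold. In the cannibalism list, the Skf and Sdp toxins with their immunity genes, none of 11 tested genes passed in edgeR or limma-voom, and 4 were higher and 1 lower in DESeq2, and 1 was higher without wild-type replicate 3 in edgeR. The block gave 7 higher and 2 lower, and total counts 2 lower. With adjustment over the list alone 9 were higher and 2 lower, the same counts as at an unadjusted p under 0.05. The values of skfA (0.90, SE 0.22), skfB (0.83, SE 0.20) and skfC (0.79, SE 0.20) had edgeR adjusted p of 0.0591, 0.0591 and 0.065, whereas sdpR stood at -1.02 (adjusted p = 0.0984). By camera the list had an adjusted p of 0.00255, and an adjusted p = 0.793 with an estimated correlation. In the surfactin operon none of 5 genes passed in edgeR, DESeq2 or limma-voom, 1 had an unadjusted p under 0.05, and the median was 0.51, with comS at 0.56 (adjusted p = 0.215), srfAD at 0.62 (adjusted p = 0.256) and srfAA at 0.51 (adjusted p = 0.275). Limma's camera put the list at an adjusted p of 0.024, lost without wild-type replicate 2 (0.0917) or mutant replicate 1 (0.129), and an adjusted p = 0.793 with an estimated correlation. Among peptide and polyketide antibiotics none of 28 genes passed in edgeR or limma-voom, 6 were higher in DESeq2, 2 with the block and 7 at an unadjusted p under 0.05. Genes of the subtilosin cluster had the smallest p, albG (1.42, adjusted p = 0.0957), albF (1.503, adjusted p = 0.0957) and sboX (1.195, adjusted p = 0.106). The list's median of 0.10 turned to -0.14 with total counts and ran from 0.03 to 0.32 when each library was left out in turn. Camera gave an adjusted p of 0.0421, lost without wild-type replicate 2 (0.165) or mutant replicate 2 (0.244), and an adjusted p = 0.793 with an estimated correlation. Of 8 extracellular protease genes 1 fell, epr (-2.95, adjusted p = 0.0212), a call lost without each mutant library in turn, with 2 lower in DESeq2 or with the block and 0 in limma-voom, and camera gave an adjusted p of 0.635.

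Biosynthesis lists gave few single-gene calls. All 13 purine synthesis genes had negative values (median -0.50), with purL (-0.63), purD (-0.67) and purC (-0.60) at edgeR adjusted p of 0.058, 0.0752 and 0.0852. None passed in the main edgeR fit or limma-voom, 3 were lower in DESeq2, 4 with total counts, 7 with the block and 1 with at least 50 counts in 3 libraries, and 8 were lower both at an unadjusted p under 0.05 and when adjusted over the list alone. The camera test of the list had an adjusted p of 1.58e-05, and an adjusted p = 0.662 with an estimated correlation. In tryptophan synthesis 1 of 8 genes fell, trpE (-0.93, SE 0.18, adjusted p = 0.025), and 4 did so when adjusted over the list alone, with trpD (-0.76) and trpF (-0.78) next. The trpE call was lost without wild-type replicate 1, wild-type replicate 2, mutant replicate 2 or mutant replicate 3, whereas 3 genes were lower in DESeq2 and 4 with total counts or the block. Camera gave the list an adjusted p of 0.0323, lost without wild-type replicate 1 (0.127), wild-type replicate 3 (0.0546), mutant replicate 2 (0.068) or mutant replicate 3 (0.121), and an adjusted p = 0.793 with an estimated correlation. In arginine synthesis all 9 values were negative (median -1.02, between -1.83 and -0.02 when each library was left out in turn), led by argG (-1.45), argC (-1.02) and argH (-1.19), with none past the threshold in the main edgeR fit, DESeq2 or limma-voom, 1 lower with the block and 1 at an unadjusted p under 0.05. In limma's camera test the adjusted p was 0.0362, lost without wild-type replicate 2 (0.487), mutant replicate 1 (0.283), mutant replicate 3 (0.0716) or both libraries numbered 1 (0.203), and an adjusted p = 0.913 with an estimated correlation. In fatty acid synthesis none of 15 genes passed in the main edgeR fit, DESeq2 or limma-voom, 3 were higher and 2 lower with the block, and 3 had an unadjusted p under 0.05, among them fabD (0.66), fabG (0.80) and desR (-0.76). By camera the list had an adjusted p of 0.0421, lost without wild-type replicate 2 (0.177), wild-type replicate 3 (0.157) or mutant replicate 1 (0.431), and an adjusted p = 0.913 with an estimated correlation.

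Other lists did not pass the camera test. For iron acquisition, branched-chain amino acid, histidine and pyrimidine synthesis, use of arginine and histidine, phospholipid and lipoteichoic acid, PBSX prophage and SigB general stress, no member passed in edgeR or limma-voom, and camera gave adjusted p of 0.239, 0.673, 0.726, 0.726, 0.823, 0.219, 0.624 and 0.269. In DESeq2 and with the block 1 iron gene was higher and 2 SigB genes were lower, the latter also with total counts, and at an unadjusted p under 0.05 there were 5, 0, 0, 0, 1, 1, 0 and 3 genes in these lists. The SigB list passed camera without wild-type replicate 3 (adjusted p = 0.00656) or mutant replicate 1 (0.00275), and 1 of its genes was lower without wild-type replicate 2. Of 17 heat shock and protein quality genes groEL (1.79, SE 0.24, edgeR adjusted p = 0.00505) and dnaK (0.94, adjusted p = 0.0208) rose and htrA (-1.17, adjusted p = 0.0452) fell, with 4 higher and 5 lower when adjusted over the list alone, and camera gave an adjusted p of 0.51. The dnaK call was lost without wild-type replicate 1, mutant replicate 1 or mutant replicate 2, that of htrA when any library other than wild-type replicate 2 was left out, and all 3 without both libraries numbered 1. There were 3 higher and 3 lower in DESeq2, 2 and 0 in limma-voom, 2 and 2 with total counts and 5 and 3 with the block. Of 46 alternative carbon source genes 1 rose, the glycerol phosphate permease gene glpT (1.19, adjusted p = 0.0197), a call lost without wild-type replicate 1, mutant replicate 1 or mutant replicate 2. In this list 3 other genes rose without wild-type replicate 1 and 5 fell without mutant replicate 3, while 4 rose and 3 fell in DESeq2, 4 rose with the block and 2 with total counts. Camera gave it an adjusted p of 0.526, which passed without wild-type replicate 3 (0.0128) or mutant replicate 3 (0.0463). The poly-gamma-glutamate list had 0 members with a matching name and was not analysed here.

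Ribosomal RNA took a larger share of the counts in the mutant. It was 2.48% ± 0.942 in the wild type, where the libraries held 2.00%, 3.56% and 1.87%, and 6.12% ± 0.117 in the mutant (SD, n = 3 libraries each). All libraries had been depleted of rRNA before sequencing, per the labels. The 10 copies each of the 16S, 23S and 5S genes had median log2 fold changes of 1.89, 1.43 and 1.69, and the copies of each kind share near-identical sequence, so reads could be split between them. Calls of all 10 16S copies and of rrnB-5S held when each library was left out in turn. Those of all 10 23S copies were lost without wild-type replicate 1 or mutant replicate 2, and those of the other 5S copies without mutant replicate 2. Without both libraries numbered 1, 1 rRNA gene passed. Of 49 tested ribosomal protein genes 47 had positive values (median 0.51, and 0.34 to 0.67 with each library left out), and none passed in the main edgeR fit, DESeq2 or limma-voom, while 5 were higher with the block, 20 at an unadjusted p under 0.05 and 0 when adjusted over the list alone. The smallest p were those of rpmB (0.51), rpsB (0.60) and rpsT (0.81), with edgeR adjusted p of 0.146, 0.162 and 0.167. Camera gave the list an adjusted p of 2.92e-08, and an adjusted p = 0.793 with an estimated correlation. Of 78 tested tRNA genes 74 had positive values (median 0.66) and none passed in edgeR, the lowest adjusted p being 0.078.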

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

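The omission of both libraries numbered 1 and the filter of 10 counts in 3 libraries were chosen after seeing the data, and the other settings before. All 179 genes kept their direction in every setting in which they were tested (165 of them with at least 50 counts in 3 libraries). The samI change stayed between -6.21 and -5.60 when each library was left out in turn. DESeq2 called 392 genes (165 higher, 227 lower, 253 at least 2-fold, 135 higher other than rRNA genes), among them 177 of the 179, and the cause was not tested. Without both libraries numbered 1, 33 genes passed (2 higher, 31 lower, 33 at least 2-fold, 1 higher other than rRNA genes) from fewer samples, 32 of them among the 179. Leaving out rRNA and tRNA genes left 36 higher, against 42 higher other than rRNA genes in the main fit, and total counts gave 204 lower, with the median of all genes at -0.23. Leaving out 1 library gave 59 to 180 genes (19 to 65 higher, 40 to 117 lower, 59 to 169 at least 2-fold, 8 to 43 higher other than rRNA genes) and 14 to 19 lists. The other settings (RLE factors, limma-voom, no filter, the filters of 50 and 10 counts and the 1.2-fold test) gave 147 to 181 genes. With an estimated correlation 0 of 18 lists were called. Fry called 7: fla/che operon, SigD regulon, SigK regulon, biofilm matrix, glycolysis, sulfur amino acid synthesis, and SPbeta and ICEBs1. The other 11 were not called by fry, among them SigM (fry adjusted p = 0.177), phosphate starvation (0.316) and ribosomal proteins (0.316). Camera on the edgeR statistics, the block and RLE factors each kept all 18, and the omission of both libraries numbered 1 kept 17. With the replicate number as a block 457 genes passed (209 higher, 248 lower, 179 higher other than rRNA genes), including 175 of the 179. Deviations of same-numbered libraries correlated at 0.549, 0.212 and 0.095. The libraries numbered 1 correlated at -0.376 to -0.217 with those of the other strain numbered 2 or 3. Deviations within a strain sum to 0, so the positive 0.549 requires negative values among these, and they add no evidence. A factor shared by the libraries numbered 1 stays open. Wild-type replicate 2 correlated best with mutant replicate 3 (0.228) and wild-type replicate 3 with mutant replicate 2 (0.179). The numbers were not taken to pair the samples, since the labels tie none to a shared day or batch. At this depth and replication the simulated test missed most 2-fold changes, recovering 41 of 100.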

Other observations

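Apart from rRNA genes and samI, 74 called genes matched no list by name, 15 of them in ICEBs1, among these ydcL. Genes named here were chosen after their values were seen. In the mutant glmS, which makes glucosamine phosphate for the cell wall, rose from 959 ± 134 to 4086 ± 1546 CPM (log2 fold change 2.09, edgeR adjusted p = 0.00935, n = 3 libraries each). The gluconeogenic dehydrogenase gene gapB fell from 749 ± 344 to 98.3 ± 61.1 CPM (-2.93, adjusted p = 0.0123), while gapA, which works in the glycolytic direction, rose by 2.15 (adjusted p = 0.0212). The polyamine synthesis gene speD fell by 1.89 (adjusted p = 0.0168). The maltose genes malP (-1.13, adjusted p = 0.0452) and malR (-1.28, adjusted p = 0.0313) fell, as did frlB (-3.96, adjusted p = 0.00873), frlN (-3.56) and frlO (-4.69) for use of fructosamines. The pyrimidine nucleoside phosphorylase gene pdp rose by 1.34 (adjusted p = 0.00713), and the magnesium transporter gene mgtE rose by 1.97 (adjusted p = 0.00801). The calls of glmS, pdp and mgtE held when each library was left out in turn. Those of gapB and frlB were lost without mutant replicate 2, those of gapA, speD, frlN and frlO also without mutant replicate 1, and those of malP and malR without either of these or wild-type replicate 1 or 2, with frlN also lost without mutant replicate 3 and malP without wild-type replicate 3.

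The cell wall hydrolase gene lytE (-1.26, adjusted p = 0.0184) and mreBH (-1.70, adjusted p = 0.0212), whose product guides it, both fell in edgeR's test. The gene rapF and its peptide gene phrF rose, by 1.35 (adjusted p = 0.0266) and 1.21 (adjusted p = 0.0274), opposite in direction to rapA and phrA. Both fbpA (-1.06, adjusted p = 0.0103) and fbpB (-1.09, adjusted p = 0.00935), genes for helpers of the iron-sparing response, fell, although no gene of the iron acquisition list passed in edgeR. The genes mtnE (-2.05, adjusted p = 0.0134) and mtnU (-1.93, adjusted p = 0.0144) and the annotated RNAs mswC (-3.72) and mswD (-1.78), which lie between mtnK and mtnW in gene order, also fell. The calls of mtnE and mswC held when each library was left out in turn, that of mtnU was lost without mutant replicate 3, and that of mswD was kept only without wild-type replicate 1. Those of fbpA and fbpB were lost without mutant replicate 2, those of lytE and mreBH also without wild-type replicate 1 and 1 other mutant library each, and those of rapF and phrF without wild-type replicate 1, wild-type replicate 2, mutant replicate 2 or mutant replicate 3.

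For the patterns weighed here, the tests of the splits, of the shares of carried-over reads by chi-square, of calls without rRNA and of phosphate genes without mutant replicate 2 were planned before their results were seen, and the others were chosen afterwards. Of the 10 ways to split the 6 libraries into 3 and 3, only the real one gave as many as 179 genes and the highest other gave 0, but 10 splits are too few for a share under 0.05. Every other split also mixes the strains, so the strain difference widens the spread within its groups and makes calls unlikely. The value of 0 is therefore no measure of calls without a strain difference.

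The protein-coding genes from xis to yddI and mtnK and mtnA held almost no counts in the mutant. Absence of the whole ICEBs1 element is argued against by its outer genes, which kept at least 13.4% of the wild-type level in every mutant library, against 0.874% to 2.39% for samI. Deletion of the segment with wild-type reads carried over at a uniform share is argued against by shares that differed between genes, from 0.148% of the wild-type counts for conB to 1.86% for conG. The planned chi-square (p of at most 1.62e-07 for each wild-type source, without conG) covers counting error only. Against the spread between libraries (edgeR SE) p was 2.82e-07 over the 18 genes and 0.00102 without conG, with as few as 5 mutant counts in a gene. Among genes with at least 2000, 4000 or 12000 wild-type counts and without conG it was 0.0523, 0.0805 and 0.394, so the evidence rests on conG and the genes with few counts, which limits it. Deletion with counts left from sources that differ between genes was not tested and stays open. Inside the segment the annotated RNA sncO held 29 mutant counts against 70 in the wild type (41.4%), more than carry-over at the segment's share would leave. This is 1 gene with few counts, and the strand setting of the counting was not given, so it does not decide the question. The share left over the segment's protein-coding genes was 0.417% (exact 95% interval 0.384 to 0.452). It overlaps that of mtnK and mtnA, 0.458% (0.401 to 0.52), although conB, the segment's lowest gene, had 0.0766 to 0.259. Carried-over reads therefore cannot be told apart from low expression of mtnK and mtnA. Whether both are deleted in part cannot be told apart either, because at most 0.622% of their wild-type level was left, below that of samI. Between mtnK and mtnW, the RNA mswC held 100, 125 and 116 mutant counts against 1336, 2715 and 1680 in the wild type. Carry-over at the share of mtnK and mtnA would leave fewer. As mswC is another gene, it does not decide whether mtnK and mtnA are present. Whether these changes follow from loss of samI or from another difference between the strains was not tested. Genome sequence of both strains, which was not among the files, would decide whether the genes are present.

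The rRNA genes were higher in the mutant. With total counts, where the rRNA share enters every fold, rRNA genes moved the log2 fold changes of the 149 other called genes by a median of -0.054 and at most 0.059. The rRNA shares alone fix the size of this move, so it could not have come out otherwise. It shows only how little the shares add at this scaling, where the smallest of these log2 fold changes was 0.486 in size. The folds of the main fit, scaled by TMM and with a median SE of 0.32, were not tested by it. Without rRNA and tRNA genes 124 of their calls were kept and 25 ended with adjusted p of 0.0502 to 0.0617, of which 20 still had an unadjusted p at or under 0.00217, the highest of a called gene before, so that the adjustment over fewer small p ended these. Less complete depletion of the mutant libraries cannot be told apart from more rRNA in the cells, because 0 tRNA or ribosomal protein genes passed in edgeR although their medians were positive.

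Most phosphate starvation genes were highest in mutant replicate 2, but phoP and phoR were highest in wild-type replicate 2 and pstA was as high in wild-type replicate 1. That library alone does not account for the list's median, which stayed at 1.30 without it, although no member then passed in edgeR. In wild-type replicate 1 pstS stood at 328 CPM, against 39.9 and 114 in wild-type replicates 2 and 3, so these genes also varied within the wild type. No biological explanation for the spread was tested, since the labels separate the libraries only by strain.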
